A study of Mus musculus with 6 samples.

How the data were processed

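RNA from fat tissue of NOD mice, a strain that develops autoimmune diabetes, was measured on 6 Affymetrix mouse arrays, 2 for each of 3 groups. Per the labels, the groups were normoglycemic females of 10 weeks, mice with blood glucose over 300 mg/dl for 3 consecutive days, and mice treated with alpha-1-antitrypsin (AAT) that had reverted and no longer needed insulin. Total RNA was extracted with Trizol and labelled with biotin by the single-cycle protocol, per the labels' protocols. The labels do not say whether the 2 arrays of a group came from separate mice, so the p-values measure only the spread between these samples, which could be technical. They give age and sex for the normoglycemic group alone.

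The deposited values are intensities on a linear scale, 1 signal for each of 45101 probe sets per array, computed with MAS5 per the submitters' processing notes (version not given in the sources used here). MAS5 subtracts background and mismatch signal on each array separately and scales each array by a constant. The mean signal without the lowest and highest 2% of probe sets was within rounding of 500 on every array, so the authors' scaling was kept. Detection calls were not used here. The median signal of an array ran from 175.7 to 272, and the number of arrays limits the precision.

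Gene names came from the platform's probe annotation, updated through the RefSeq gene table. Apart from 64 control probe sets, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none; 34741 matched the RefSeq table by gene identifier, and 0 symbols had to be changed. Probe sets with several symbols or none were left out. No genome build was named for the annotation, so no coordinates are given. Values were taken as log2(signal + 75), where 75 is the 25th percentile of the deposited values, so that differences of weakly expressed genes are understated. Probe sets with a mean signal over the 6 arrays above 164 (the 40th percentile) were kept, 27022 in number, and the probe set with the highest mean stood for its gene, which gave 13040 genes.

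Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on 3 group means over all 6 arrays, eBayes with trend, 2-sided; statmod 1.5.0 for the robust alternative), with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The fit had 3 residual degrees of freedom and 5.36 prior ones. All values of a gene given as ± SE carry the moderated standard error of this fit. An exact permutation test of 2 arrays against 2 could not give a p below 0.333, so none was run.

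Gene lists numbering 31 were fixed before the data were examined. They cover lipogenesis, cholesterol synthesis, insulin signalling, adipocyte identity, fasting and fatty acid oxidation, brown fat, oxidative phosphorylation, macrophages, T cells, B cells, lymph node stroma, neutrophils, inflammation, the interferon response, MHC class II, extracellular matrix, ER stress, glucocorticoid response, circadian clock, cell cycle, antioxidant defence, immediate early genes, endothelium, skeletal muscle, smooth muscle, pancreas, mammary epithelium, mesothelium, erythroid and platelet genes, sex-linked transcripts and the Serpina1 family. The Serpina1 list also holds Serpina3n and other Serpina genes. Lists with fewer than 5 measured genes (the sex-linked and Serpina1 lists) were given as values. The other 29 were tested in 3 contrasts with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 87 tests, and beside it with the correlation estimated from the data and with fry. Members past the threshold were also counted after adjustment over the list alone. Some lists share genes, among them Ctss, Gpd1, Dusp1 and Slc2a4, so their tests are not independent.

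The genes named were chosen by a rule fixed in advance. For each contrast it took the 10 largest rises and falls among genes past the threshold whose groups did not overlap; where none passed, the 5 genes of each direction with the smallest unadjusted p, given as values. It added the 4 members with the smallest p in the direction of each list that camera called, and always Slc2a4, Insr, Irs1, Irs2, Adipoq, Lep, Tnf, Il6, Ccl2, Pparg, Fasn and Scd1. Tnf, Il6 and Ccl2 lay under the signal filter. A gene named outside this rule is said to have been chosen after its values were seen.

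The limma step was tested on simulated data with 200 changed genes among the 13040, using the spread of these arrays. In the diabetic against normoglycemic contrast it recovered 3.66% of 2-fold, 55.4% of 4-fold and 86.8% of 8-fold changes at 8 false calls a run; for AAT-treated against diabetic the shares were 3.96%, 55.8% and 88.6% at 8.6 false calls. With no change simulated, AAT-treated against normoglycemic gave 0.45 false calls a run. For the comparisons that share the diabetic arrays, overlaps of genes at an unadjusted p under 0.05 were set against 100 draws of unchanged groups, with variances drawn from limma's prior and the same fit. Correlations in fits with other arrays or the covariate were set against 200 draws in the same design. All draws took genes and arrays as independent. The list tests were tested on simulated lists of 25 genes: with a correlation of 0.16 and no shift, camera with the preset correlation gave an unadjusted p under 0.05 in 38% of 100 runs and camera with an estimated correlation in 3%; with a log2 shift of 1 the shares were 100% and 95%.

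The replicate numbers are shared by the groups, and nothing in the labels says that they pair arrays. Alternatives fixed before the data were examined were quantile normalization, median centring, no pseudocount or a smaller one, no filter or a stricter one, every probe set in place of a chosen one, eBayes without trend or robust, a fit of only the groups compared, other thresholds, the replicate number as a block, an estimated inter-gene correlation, and leaving out each array in turn. A crossed replicate block, the level of the hybridisation controls as a covariate, and a fit without the 2 arrays with the brightest hybridisation controls were chosen after seeing the data.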

Results

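Fat tissue of NOD mice was profiled on 6 arrays, 2 each from normoglycemic mice, diabetic mice, and mice treated with alpha-1-antitrypsin (AAT), a serum protease inhibitor, whose diabetes had reverted. The design implies 3 comparisons: diabetic against normoglycemic, AAT-treated against diabetic, and AAT-treated against normoglycemic. Log2 differences of genes are given ± SE from limma with n = 2 arrays per group.

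The arrays differed in technical measures. The ratio of 3' to 5' signal of the beta-actin control probe sets, which rises as RNA is degraded or incompletely copied, was 3.63 and 4.30 in normoglycemic fat. It was 15.2 and 15.5 in diabetic fat and 9.08 and 5.87 in AAT-treated fat. The same ratio for the Gapdh control was 0.91 and 0.95 in normoglycemic, 2.46 and 4.63 in diabetic, and 2.31 and 0.79 in AAT-treated fat. Its group means had the order of those of beta-actin, but AAT-treated 2 lay below both normoglycemic arrays. The mean signal of the hybridisation controls, transcripts added in fixed amounts, was 71077 on normoglycemic 1 and 43841 on AAT-treated 2, against 11599 to 23851 on the other arrays. Every array was scaled to about the same mean signal, so these values are relative to the signal of the sample itself. Arrays called bright below are so named for these controls alone, as is hybridisation brightness. Normoglycemic 1 and AAT-treated 2 stood apart on the first principal component (46.2% of the variance), at −0.73 and −0.34. The other 4 lay between 0.05 and 0.42. Across genes, normoglycemic 1 and 2 correlated at 0.836, below the 0.922 of normoglycemic 2 with AAT-treated 1. No arrays held identical values. Signal of Xist, expressed from the inactive X chromosome, was 7055 or more on all 6 arrays. The Y-linked genes lay under the mean-signal filter, at 55.2 or less for Eif2s3y, 155 or less for Kdm5d and 244 or less for Uty. Each of these genes had its highest signal on normoglycemic 1, labelled female. With the Xist signals, this argues against male samples in the other groups.

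**Figure D1:**
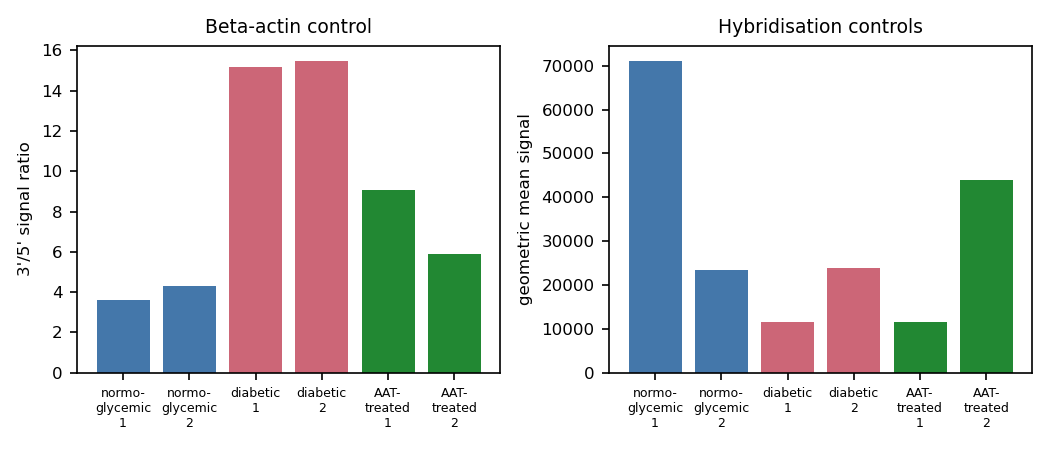
Control probe sets on each of the 6 arrays: left, the 3' over 5' signal ratio of beta-actin; right, the geometric mean signal of the hybridisation controls, both on linear axes with bars from 0. The diabetic arrays had beta-actin ratios of 15.2 and 15.5, and normoglycemic 1 and AAT-treated 2 had the brightest hybridisation controls (71077 and 43841).

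Diabetic fat held more transcripts of fat synthesis than normoglycemic fat. Of the 25 lipogenic genes 24 were higher, with a median log2 difference of 0.98, and the list rose by camera (adjusted p = 3.48e-11; adjusted p = 0.419 with an estimated correlation). The mean level of the list was 12.77 ± 0.32 (SD, n = 2) in diabetic and 11.62 ± 0.42 in normoglycemic fat. Acss2, which makes acetyl-CoA from acetate, differed by 2.18 ± 0.34, and Acly, which makes it from citrate, by 2.03 ± 0.35. The acyltransferase Agpat2 differed by 1.82 ± 0.37 and Pnpla3 by 2.56 ± 0.57. Adjusted over the list alone 8 members passed, and 0 over all genes. Without normoglycemic 1 the list's median was 1.55.

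The cholesterol synthesis list rose too, with 13 of 16 genes higher and a median of 0.56 (adjusted p = 0.00148; adjusted p = 0.414 with an estimated correlation). Its leading member was Insig1, which holds back sterol synthesis (2.48 ± 0.34). The synthesis enzymes Cyp51, Lss and Hmgcs1 differed by 1.97 ± 0.58, 1.39 ± 0.51 and 0.94 ± 0.33. With p adjusted over the list alone 1 member passed. The cholesterol call was lost without diabetic 2 (adjusted p = 0.0669).

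Macrophage genes were higher in diabetic fat, 23 of 28 with a median of 0.73, and the list rose (adjusted p = 7.98e-07; adjusted p = 0.414 with an estimated correlation). The lectin Clec10a differed by 2.62 ± 0.57 and the complement gene C1qb by 2.12 ± 0.49. The receptor Csf1r differed by 1.88 ± 0.45 and the protease Ctss by 1.45 ± 0.38. Adjusted over the list alone 7 members passed, and 0 over all genes. Without diabetic 2 the median was 0.43. Erythroid and platelet genes fell, 7 of 7 lower with a median of −1.75 (adjusted p = 9.57e-06; adjusted p = 0.414 with an estimated correlation). The platelet chemokine Ppbp differed by −3.49 ± 0.47 and the red cell anion exchanger Slc4a1 by −2.64 ± 0.41. Hbb-b2 differed by −3.25 ± 0.87 and Alas2, of haem synthesis, by −1.75 ± 0.79. In this list 3 members passed over the list alone, and its median without normoglycemic 2 was −1.13. The means of both lists were ordered normoglycemic, AAT-treated, diabetic or the reverse, as was the beta-actin ratio.

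Immediate early genes, which respond to stimuli within minutes, fell in diabetic fat, with 12 of 17 lower and a median of −0.32 (adjusted p = 0.0068; adjusted p = 0.68 with an estimated correlation). The transcription factors Egr1 and Fos differed by −2.92 ± 0.49 and −2.34 ± 0.52. The mRNA decay factor Zfp36 differed by −1.59 ± 0.33 and the phosphatase Dusp1 by −1.40 ± 0.41. With p adjusted over the list alone 4 members passed. The immediate early call was lost without diabetic 1 (median −0.03, adjusted p = 0.147) and without normoglycemic 2 (adjusted p = 0.487). The median was −0.87 without diabetic 2 and −1.0 without normoglycemic 1.

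Antioxidant genes fell, with 18 of 24 lower and a median of −0.51 (adjusted p = 0.00489; adjusted p = 0.565 with an estimated correlation). Gpx1 differed by −1.45 ± 0.39, Gsta3 by −2.23 ± 0.68, Gclm by −1.81 ± 0.61 and Prdx3 by −1.02 ± 0.37. Without diabetic 1 the adjusted p was 0.0962. Cell cycle genes fell, with 17 of 21 lower and a median of −0.47 (adjusted p = 0.0187; adjusted p = 0.414 with an estimated correlation). Cdk1 differed by −1.71 ± 0.63, Ube2c by −1.17 ± 0.43, Pcna by −1.03 ± 0.30 and Ccna2 by −0.99 ± 0.40. Without normoglycemic 2 the adjusted p was 0.169. In both lists 0 members passed over the list alone. The means of both lists also followed the order of the beta-actin ratio, in reverse.

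The extracellular matrix list rose, with 24 of 31 genes higher and a median of 0.54 (adjusted p = 0.000261; adjusted p = 0.68 with an estimated correlation). The collagens Col5a3 and Col1a1 differed by 1.76 ± 0.60 and 1.37 ± 0.44, the crosslinking enzyme Loxl1 by 1.11 ± 0.31 and the protease Mmp2 by 1.10 ± 0.32. Its median was 0.06 without diabetic 2 (adjusted p = 0.476) and 0.31 without normoglycemic 1 (adjusted p = 0.076). It was 1.12 without diabetic 1 and 0.93 without normoglycemic 2. The mean of the matrix list followed the order of the beta-actin ratio. Interferon-response genes rose, with 19 of 29 higher and a median of 0.18 (adjusted p = 0.0343; adjusted p = 0.726 with an estimated correlation). The GTPases Gbp6, Iigp1 and Gbp3 differed by 1.96 ± 0.49, 1.31 ± 0.33 and 1.11 ± 0.36, and the peptide transporter Tap1 by 1.44 ± 0.56. Their median was 0.03 without diabetic 2 (adjusted p = 0.638) and 0.14 without normoglycemic 1 (adjusted p = 0.105). It was 0.42 without diabetic 1 and 0.34 without normoglycemic 2.

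Lymph node stroma genes rose, with 5 of 6 higher and a median of 0.73 (adjusted p = 0.0401; adjusted p = 0.463 with an estimated correlation). Lyve1 differed by 1.93 ± 0.79, Ltb by 1.61 ± 0.57, Clu by 0.84 ± 0.34 and Mfge8 by 0.62 ± 0.51. Of the 12 genes on this list 6 were measured. Glycam1, Ccl19 and the Ccl21 genes were not kept, so the rise does not show lymph node stroma in the fat. The stroma call was lost without AAT-treated 2 (adjusted p = 0.0546), diabetic 2 (0.193) or normoglycemic 2 (0.137). Without normoglycemic 1 Mfge8 differed by −0.090. In the matrix, interferon and lymph node stroma lists 0 members passed over the list alone.

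By limma, 0 of 13040 genes passed the adjusted threshold between diabetic and normoglycemic fat. At an unadjusted p under 0.05 there were 1291 genes (688 higher, 603 lower), where chance gives 652. The groups did not overlap for 44.7% of genes, and chance gives 33.3%. Among the genes with the smallest p, Laptm5 (2.34 ± 0.34), Coro1a (2.12 ± 0.35) and Tgfbi (2.08 ± 0.32) had higher values in diabetic fat. Mycl (−3.24 ± 0.45) and Anp32a (−2.67 ± 0.32, adjusted p = 0.245, the smallest) had lower ones. The other 2 kept probe sets of Anp32a differed by −0.74 and −0.10. The insulin-regulated glucose transporter Slc2a4 differed by 1.07 ± 0.46, the insulin receptor Insr by 1.01 ± 0.51, Irs1 by −0.02 ± 0.34 and Irs2 by 0.73 ± 0.63. The adipokines Adipoq and Lep differed by −0.52 ± 0.55 and 0.48 ± 2.0. Pparg differed by −0.93 ± 0.37, Fasn by 1.60 ± 0.70 and Scd1 by −0.36 ± 0.49, and Scd1 was at 0.17 with quantile normalization. Fasn signals were 31130 and 6093 in normoglycemic and 30725 and 56987 in diabetic fat, and its difference was 2.76 without normoglycemic 1 and 0.43 without normoglycemic 2. Of 54 genes named in this comparison and kept by the filter, 23 differences moved by over 1.5 times without 1 of the arrays, and 5 of them turned. Irs2 was at 0.0046 without normoglycemic 1. Tnf (0.05 ± 0.39), Il6 (−0.47 ± 0.42) and Ccl2 (−1.09 ± 0.67) were under the signal filter. Other kept probe sets had the opposite sign for Acly (2 of 3), Laptm5 (2 of 4), Insr (2 of 2), Hmgcs1 (1 of 4) and Clu (1 of 3). The same held for the single other probe set of Gsta3, Hbb-b2 and Scd1.

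AAT-treated fat held fewer lipogenic transcripts than diabetic fat. Of the 25 genes 24 were lower, with a median of −1.50, and the list fell (adjusted p = 8.03e-22; adjusted p = 0.414 with an estimated correlation). Fasn, the fatty acid synthase, differed by −3.01 ± 0.70, and its regulator Mlxipl by −2.66 ± 0.57. Agpat2 differed by −2.53 ± 0.37, Acss2 by −2.17 ± 0.34 and Acly by −2.04 ± 0.35. Adjusted over the list alone 16 members passed, and 0 over all genes. The list's mean level was 11.27 ± 0.20 (SD, n = 2) in AAT-treated fat, below that of normoglycemic fat, and so did not follow the order of the beta-actin ratio.

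Cholesterol synthesis genes fell in AAT-treated against diabetic fat, with 15 of 16 lower and a median of −0.48 (adjusted p = 1.28e-05; adjusted p = 0.414 with an estimated correlation). Insig1 differed by −2.69 ± 0.34, Fdft1 by −1.78 ± 0.42, Cyp51 by −1.17 ± 0.58 and Sc5d by −1.07 ± 0.42. With p adjusted over the list alone 2 members passed. Without diabetic 1 the median was −0.89.

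**Figure D2:**
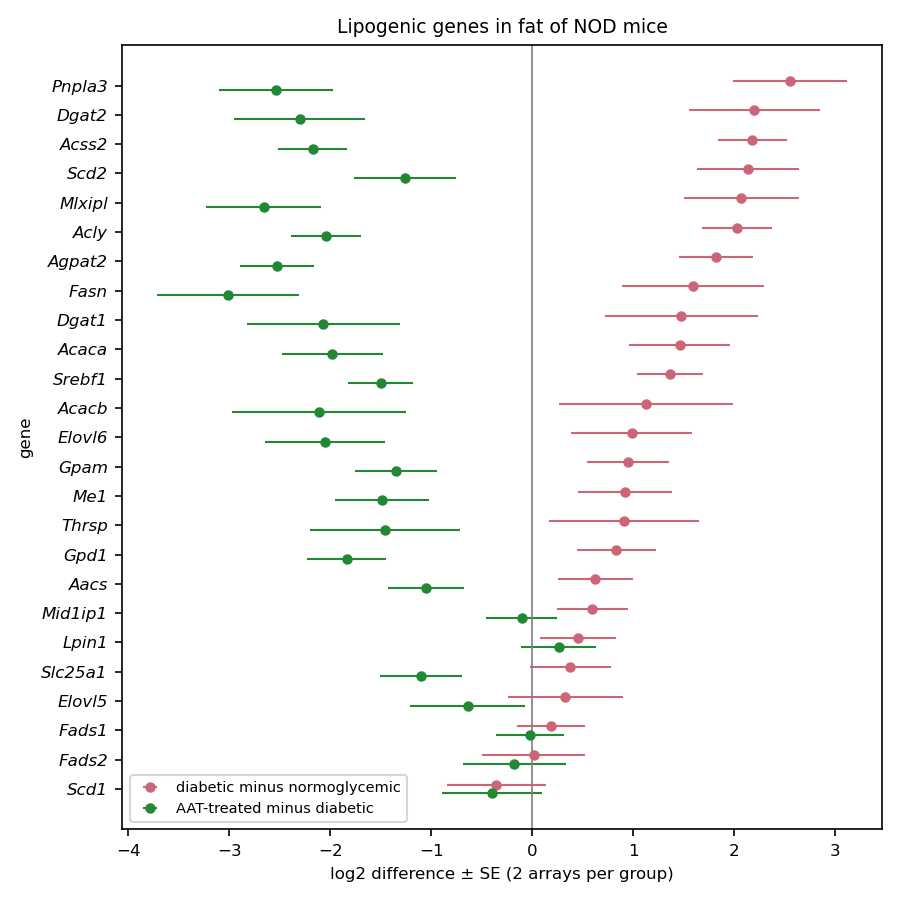
Log2 difference ± SE of the 25 lipogenic genes in diabetic minus normoglycemic fat and in AAT-treated minus diabetic fat, with 2 arrays per group; both contrasts share the diabetic arrays. In the first contrast 24 genes lay above 0, and in the second 24 lay below it.

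Smooth muscle genes had the largest median shift of the 29 lists tested. In AAT-treated against diabetic fat 11 of 11 were higher, with a median of 2.78, and the list rose (adjusted p = 2.5e-20; adjusted p = 0.414 with an estimated correlation). The calponin Cnn1 differed by 3.51 ± 0.66 and the actin Actg2 by 3.10 ± 0.56. The myosin light chain Myl9 differed by 2.91 ± 0.52 and the intermediate filament gene Des by 1.81 ± 0.37. Adjusted over the list alone 11 members passed, and 0 over all genes. The list's mean was 12.42 ± 0.40 (SD, n = 2) in AAT-treated, 9.78 ± 0.44 in diabetic and 10.18 ± 1.23 in normoglycemic fat, an order that differs from that of the beta-actin ratio.

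Immediate early genes rose in AAT-treated against diabetic fat, with 15 of 17 higher and a median of 0.88 (adjusted p = 1.7e-06; adjusted p = 0.525 with an estimated correlation). Egr1 differed by 2.87 ± 0.49, Fos by 2.83 ± 0.52, Zfp36 by 1.91 ± 0.33 and Ier2 by 1.67 ± 0.39. With p adjusted over the list alone 5 members passed. The median was 0.43 without AAT-treated 1 and 0.43 without diabetic 1. Glucocorticoid-responsive genes rose, with 16 of 17 higher and a median of 0.83 (adjusted p = 1.7e-06; adjusted p = 0.414 with an estimated correlation). Tsc22d3 differed by 1.46 ± 0.56, Dusp1 by 1.32 ± 0.41, Errfi1 by 1.25 ± 0.52 and Klf15 by 0.84 ± 0.34, with 0 passing over the list alone.

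Erythroid and platelet genes rose in this comparison, with 5 of 7 higher and a median of 1.53 (adjusted p = 0.00467; adjusted p = 0.414 with an estimated correlation). Ppbp differed by 2.09 ± 0.47, Hbb-b2 by 1.89 ± 0.87, Alas2 by 1.65 ± 0.79 and Slc4a1 by 1.53 ± 0.41. Adjusted over the list alone 2 members passed. Without AAT-treated 1 the median was 0.46 (adjusted p = 0.172). Macrophage genes fell, with 22 of 28 lower and a median of −0.28 (adjusted p = 0.0136; adjusted p = 0.583 with an estimated correlation). Clec10a differed by −1.22 ± 0.57, C1qb by −1.01 ± 0.49, Csf1r by −0.97 ± 0.45 and Retnla by −0.94 ± 0.46, with 0 passing over the list alone. The macrophage call was lost without diabetic 2 (median 0.02, adjusted p = 0.747) and without AAT-treated 2 (adjusted p = 0.0785), and without diabetic 1 the median was −0.63. Both lists again moved with the beta-actin ratio.

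Adipocyte identity genes fell, with 15 of 21 lower and a median of −0.49 (adjusted p = 0.0043; adjusted p = 0.697 with an estimated correlation). Gpd1 differed by −1.84 ± 0.39, Retn by −1.69 ± 0.64, Slc2a4 by −1.27 ± 0.46 and Lpl, which frees fatty acids from lipoproteins, by −1.08 ± 0.51. With p adjusted over the list alone 1 member passed. Without diabetic 2 the direction turned (median 0.14, adjusted p = 0.848), and without AAT-treated 2 the call was lost (adjusted p = 0.474). The median was −1.13 without diabetic 1 and −1.0 without AAT-treated 1. Oxidative phosphorylation genes fell, with 21 of 36 lower and a median of −0.24 (adjusted p = 0.024; adjusted p = 0.68 with an estimated correlation). Ndufa5 differed by −1.37 ± 0.43, Cox5a by −0.80 ± 0.42, Cs by −0.75 ± 0.35 and Atp5a1 by −0.72 ± 0.34, with 0 passing over the list alone. The oxidative phosphorylation call was lost without diabetic 2 (median −0.07, adjusted p = 0.508), AAT-treated 2 (0.0892), normoglycemic 1 (0.0584) or normoglycemic 2 (0.0613), and without diabetic 1 the median was −0.36.

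B cell genes rose, with 11 of 15 higher and a median of 0.32 (adjusted p = 0.0257; adjusted p = 0.68 with an estimated correlation). The immunoglobulin heavy chain Ighm differed by 3.42 ± 0.86, the joining chain Jchain by 2.79 ± 0.76, Mzb1 by 0.95 ± 0.46 and Blnk by 0.95 ± 0.50. Adjusted over the list alone 2 members passed. The B cell call was lost without AAT-treated 2 (median −0.28, adjusted p = 0.475) and without diabetic 1 (0.0699), and without AAT-treated 1 the median was 0.77. It was also lost with no filter (0.0561) and with the hybridisation-control level as a covariate (0.115). Mesothelial genes rose, with 9 of 11 higher and a median of 0.65 (adjusted p = 0.00691; adjusted p = 0.674 with an estimated correlation). Wt1 differed by 1.11 ± 0.39, Krt19 by 1.01 ± 0.67, Gpm6a by 0.65 ± 0.38 and Upk3b by 0.61 ± 0.32, with 0 passing over the list alone. The mesothelial call was lost without AAT-treated 2 (median 0.14, adjusted p = 0.237; Krt19 at −0.14) and without diabetic 2 (median 0.43, adjusted p = 0.102), and without AAT-treated 1 the median was 1.2.

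Between AAT-treated and diabetic fat 0 of 13040 genes passed by limma, and 622 had an unadjusted p under 0.05 (383 higher, 239 lower), where chance gives 652. The groups did not overlap for 33.8% of genes, and chance gives 33.3%. The genes with the smallest p included Anp32a (3.18 ± 0.32, adjusted p = 0.0749), with signals of 4817 and 4591 in AAT-treated against 414 and 491 in diabetic fat. The other 2 kept probe sets of Anp32a differed by 0.41 and 0.69. Gcnt2 (2.88 ± 0.46), Mycl (2.87 ± 0.45) and Pdk4, which holds back glucose oxidation (2.32 ± 0.32), also had higher values, and Psat1 of serine synthesis a lower one (−1.87 ± 0.33). Insr differed by −0.56 ± 0.51, Irs1 by 0.00 ± 0.34 and Irs2 by −0.11 ± 0.63. Adipoq differed by −0.49 ± 0.55, Lep by −0.73 ± 2.0, Pparg by 0.52 ± 0.37 and Scd1 by −0.40 ± 0.49. Of 57 genes named here and kept, 29 differences moved by over 1.5 times without 1 of the arrays, among them Clec10a (−0.22 without AAT-treated 2), and 6 of them turned. Under the signal filter, Tnf differed by −0.34 ± 0.39, Il6 by 0.23 ± 0.42 and Ccl2 by 0.29 ± 0.67. Other kept probe sets had the opposite sign for Acly (1 of 3), Mycl (1 of 2), Atp5a1 (1 of 2), Ighm (1 of 7), Tsc22d3 (1 of 3), Insr (1 of 2) and Hbb-b2 (1 of 1).

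**Figure D3:**
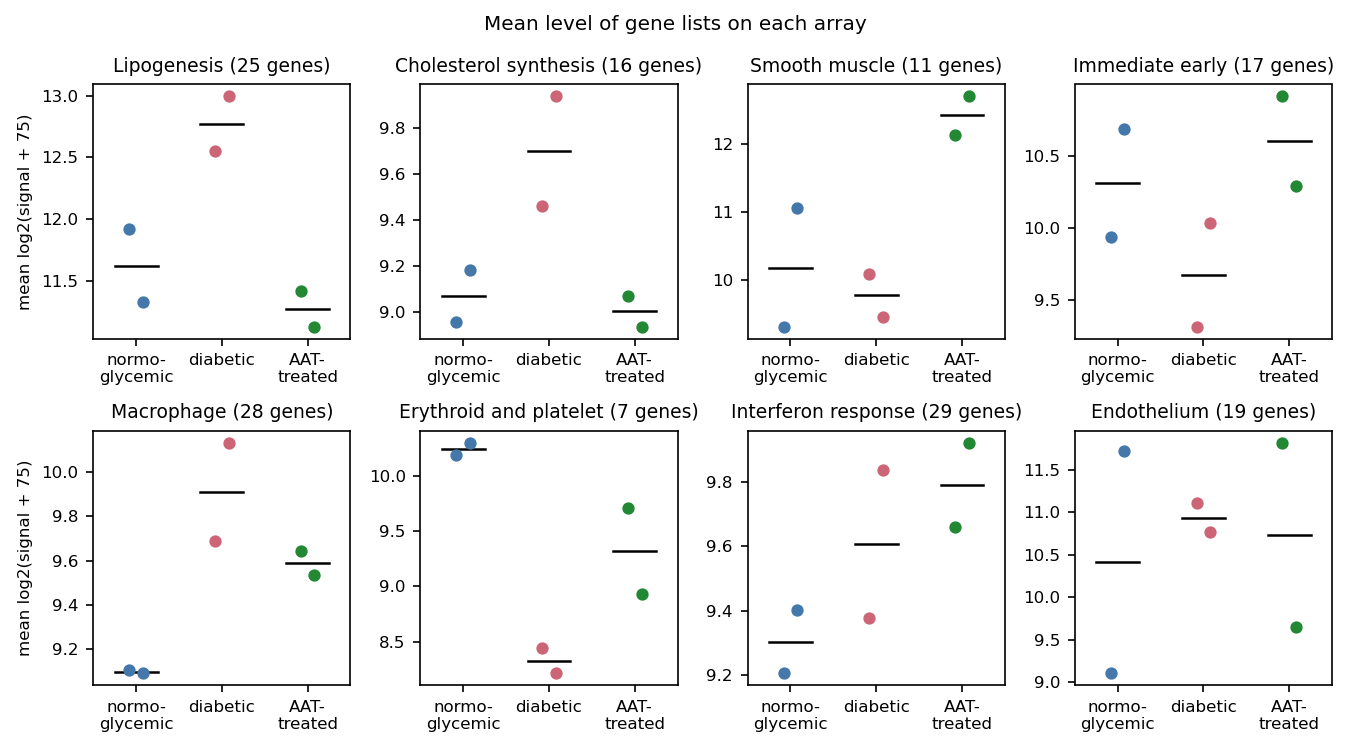
Mean log2(signal + 75) of the genes of 8 lists on each array (points) with the mean of the 2 arrays of each group (lines); the axes do not start at 0. For smooth muscle both AAT-treated arrays (12.13 and 12.70) lie above the other arrays, for lipogenesis both diabetic arrays (12.55 and 13.0) do, and the endothelial list was at 9.11 and 11.72 on the normoglycemic arrays.

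Smooth muscle genes were higher in AAT-treated than in normoglycemic fat as well. Of the list, 11 of 11 were higher, with a median of 2.15, and it rose (adjusted p = 1.39e-16; adjusted p = 0.414 with an estimated correlation). Cnn1 differed by 2.77 ± 0.66, Myl9 by 2.17 ± 0.52, Mylk by 2.14 ± 0.51 and Des by 1.56 ± 0.37. With p adjusted over the list alone 11 members passed, and 0 over all genes. Without normoglycemic 1 the median was 1.32, and without the 2 arrays with the brightest hybridisation controls it was 1.04.

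Mesothelial genes rose against normoglycemic fat, with 11 of 11 higher and a median of 0.76 (adjusted p = 1.61e-05; adjusted p = 0.468 with an estimated correlation). Gpm6a differed by 1.31 ± 0.38, Upk1b by 1.31 ± 0.61, Wt1 by 1.13 ± 0.39 and Upk3b by 0.76 ± 0.32. This mesothelial call was lost without normoglycemic 2 (median 0.50, adjusted p = 0.0694), and the median was 1.24 without AAT-treated 1 and 1.18 without normoglycemic 1. The extracellular matrix list rose, with 26 of 31 higher and a median of 0.50 (adjusted p = 2.12e-05; adjusted p = 0.674 with an estimated correlation). The matrix proteins Postn and Fbln1 differed by 1.89 ± 0.54 and 1.07 ± 0.35, the protease Mmp14 by 1.41 ± 0.37 and Loxl1 by 1.07 ± 0.31. Without AAT-treated 1 the matrix call was lost (median 0.24, adjusted p = 0.104). The matrix median was 0.81 without AAT-treated 2, 0.29 without normoglycemic 1 and 0.75 without normoglycemic 2. In the 14 called lists of this comparison other than smooth muscle, 0 members passed over the list alone.

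Interferon-response genes rose in AAT-treated against normoglycemic fat, with 27 of 29 higher and a median of 0.44 (adjusted p = 3.81e-05; adjusted p = 0.574 with an estimated correlation). Gbp6 differed by 2.02 ± 0.49, Tap1 by 1.52 ± 0.56, Gbp3 by 1.07 ± 0.36 and Oasl2 by 0.91 ± 0.39. The median was 0.21 without AAT-treated 2 and 0.66 without normoglycemic 2. Macrophage genes rose, with 21 of 28 higher and a median of 0.45 (adjusted p = 0.000257; adjusted p = 0.434 with an estimated correlation). C1qc differed by 2.10 ± 0.57, Ms4a7 by 1.35 ± 0.42, Mpeg1 by 1.29 ± 0.36 and Ctss by 1.28 ± 0.38. The beta-actin ratio was higher in AAT-treated than in normoglycemic fat, at 7.48 ± 2.27 against 3.96 ± 0.475 (SD, n = 2).

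MHC class II genes rose, with 7 of 9 higher and a median of 0.77 (adjusted p = 0.0246; adjusted p = 0.565 with an estimated correlation). The invariant chain Cd74 differed by 1.11 ± 0.58, H2-Ab1 by 0.94 ± 0.53 and H2-Eb1 by 0.91 ± 0.48. Ctss, given above with the macrophage genes, is on this list too. By limma 1 member had an unadjusted p under 0.05. The MHC class II call was lost without AAT-treated 1 (adjusted p = 0.0544), AAT-treated 2 (0.117) or normoglycemic 2 (0.226). Lymph node stroma genes rose, with 5 of 6 higher and a median of 0.72 (adjusted p = 0.00612; adjusted p = 0.414 with an estimated correlation). Ltb differed by 1.88 ± 0.57, Lyve1 by 1.43 ± 0.79, Clu by 0.89 ± 0.34 and Cxcl13 by 0.56 ± 0.49. Here too Glycam1, Ccl19 and the Ccl21 genes were not kept, so lymph node stroma in the fat is not shown. Without normoglycemic 2 the adjusted p was 0.0746.

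Glucocorticoid-responsive genes rose, with 14 of 17 higher and a median of 0.57 (adjusted p = 0.00267; adjusted p = 0.434 with an estimated correlation). Cdkn1a differed by 2.08 ± 0.71, Zbtb16 by 1.72 ± 0.47, Tsc22d3 by 1.69 ± 0.56 and Klf9 by 1.07 ± 0.35. Without AAT-treated 1 the adjusted p was 0.142, and without normoglycemic 2 the median was 0.36. Clock genes rose, with 12 of 15 higher and a median of 0.22 (adjusted p = 0.0471; adjusted p = 0.525 with an estimated correlation). Npas2 differed by 1.21 ± 0.63, Nr1d1 by 0.93 ± 0.53, Bhlhe40 by 0.76 ± 0.58 and Hlf by 0.70 ± 0.47. The clock call was lost under 8 of 14 alternatives, among them leaving out AAT-treated 1 (adjusted p = 0.174), AAT-treated 2 (median 0.47, 0.0961), normoglycemic 1 (0.241) or normoglycemic 2 (median 0.63, 0.0746). It was also lost with quantile normalization (median 0.28, adjusted p = 0.0541), no pseudocount (0.26, 0.0503) and the hybridisation-control level as a covariate (0.23, 0.0842).

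Adipocyte identity genes were lower in AAT-treated than in normoglycemic fat, 20 of 21 with a median of −0.55, and the list fell (adjusted p = 0.00208; adjusted p = 0.68 with an estimated correlation). Retn differed by −1.11 ± 0.64, Adipoq by −1.01 ± 0.55, Gpd1 by −1.0 ± 0.39 and Lpl by −0.94 ± 0.51. The call was lost without AAT-treated 2 (median −0.16, adjusted p = 0.588) and without normoglycemic 2 (median −0.26, adjusted p = 0.206), and without AAT-treated 1 the median was −0.82. The lipogenic list fell, with 19 of 25 lower and a median of −0.43 (adjusted p = 0.0352; adjusted p = 0.729 with an estimated correlation). Fasn differed by −1.42 ± 0.70, Elovl6 by −1.07 ± 0.60 and Agpat2 by −0.71 ± 0.37. Signals in the normoglycemic arrays were 31130 and 6093 for Fasn and 2806 and 618 for Elovl6. Without normoglycemic 1 these genes differed by −0.25 and −0.041, and without normoglycemic 2 by −2.59 and −2.10. Without AAT-treated 2 Agpat2 differed by −0.41. The lipogenic call was lost without AAT-treated 2 (median 0.03, adjusted p = 0.699) and without normoglycemic 1 (median −0.03, adjusted p = 0.809). Without both arrays the direction turned (median 0.10, adjusted p = 0.526), and without normoglycemic 2 the median was −0.71. It was also lost with no filter (adjusted p = 0.0812) and with the hybridisation-control level as a covariate (0.0612).

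Oxidative phosphorylation genes fell, with 32 of 36 lower and a median of −0.23 (adjusted p = 0.00598; adjusted p = 0.674 with an estimated correlation). Atp5o differed by −0.71 ± 0.39, Ndufa9 by −0.60 ± 0.33, Uqcrfs1 by −0.55 ± 0.36 and Sdhb by −0.50 ± 0.33. The adjusted p was 0.165 without AAT-treated 2 and 0.0824 without normoglycemic 1. Cell cycle genes fell, with 16 of 21 lower and a median of −0.48 (adjusted p = 0.0183; adjusted p = 0.414 with an estimated correlation). Top2a differed by −1.54 ± 0.57, Cdk1 by −1.18 ± 0.63, Foxm1 by −1.03 ± 0.39 and Cdca8 by −0.91 ± 0.38. The cell cycle call was lost without AAT-treated 1 (median −0.17, adjusted p = 0.101) and without normoglycemic 2 (adjusted p = 0.206).

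Antioxidant genes fell, with 18 of 24 lower and a median of −0.41 (adjusted p = 0.00715; adjusted p = 0.574 with an estimated correlation). Gsta3 differed by −1.23 ± 0.68, Mgst1 by −0.90 ± 0.40, Prdx3 by −0.83 ± 0.37 and Txn1 by −0.76 ± 0.42. The call was lost without AAT-treated 1 (median −0.40) and without normoglycemic 2 (median −0.40). It was also lost with the hybridisation-control level as a covariate (median −0.38, adjusted p = 0.0545). Erythroid and platelet genes fell, with 7 of 7 lower and a median of −1.03 (adjusted p = 0.00116; adjusted p = 0.414 with an estimated correlation). Ppbp differed by −1.39 ± 0.47, Slc4a1 by −1.11 ± 0.41, Hba-a2 by −1.03 ± 0.58 and Gp9 by −0.93 ± 0.56. Without AAT-treated 2 the median was −0.64 (adjusted p = 0.163).

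Between AAT-treated and normoglycemic fat 0 of 13040 genes passed by limma, and 668 had an unadjusted p under 0.05 (444 higher, 224 lower), where chance gives 652. The groups did not overlap for 32.1% of genes, and chance gives 33.3%. The genes with the smallest p were Ighm (4.89 ± 0.86), the sarcomere gene Myom1 (2.94 ± 0.47, adjusted p = 0.784), Cacna2d1 (2.38 ± 0.43), Tgfbi (1.88 ± 0.32) and Ms4a4d (1.79 ± 0.31). In the other direction they were Sema4f (−2.01 ± 0.48), Cyp2c39 (−1.90 ± 0.49), Psat1 (−1.57 ± 0.33), Urah (−1.34 ± 0.34) and Mrps18a (−1.21 ± 0.29). Slc2a4 differed by −0.20 ± 0.46, Insr by 0.45 ± 0.51, Irs1 by −0.02 ± 0.34 and Irs2 by 0.63 ± 0.63. Lep differed by −0.25 ± 2.0, Pparg by −0.41 ± 0.37 and Scd1 by −0.75 ± 0.49. Of 75 genes named here and kept, 44 differences moved by over 1.5 times without 1 of the arrays, among them Gsta3 (−0.082 without normoglycemic 1), Retn (−0.10) and Upk1b (0.25), both without AAT-treated 2, and 5 of them turned. Under the signal filter, Tnf differed by −0.29 ± 0.39, Il6 by −0.24 ± 0.42 and Ccl2 by −0.79 ± 0.67. Other kept probe sets had the opposite sign for Ighm (1 of 7), Cacna2d1 (1 of 1), Fbln1 (1 of 2), Klf9 (2 of 6), Des (1 of 1), Slc2a4 (1 of 1) and Insr (2 of 2). Of the named genes with an absolute log2 difference over 1 and other kept probe sets, 10 of 21, 11 of 19 and 5 of 21 in the 3 comparisons had no other probe set at 50% of it or more. Anp32a, Acss2, Acly and Mycl were among them in the first and second, and Gbp6 in the first and last.

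Gene lists called by camera numbered 10, 11 and 15 of 29 in the 3 comparisons with the preset correlation. With the correlation estimated from the data (median 0.159) camera called 0, 0 and 0 lists, and 3, 5 and 2 had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in a direction, called 0, 0 and 0, and its test for change in either direction called 2, 2 and 1. These were cell cycle in each comparison (adjusted p = 0.0245, 0.0245 and 0.0361), erythroid and platelet genes in the first (0.0361) and fasting and fatty acid oxidation in the second (0.0245). On simulated lists of 25 genes with a correlation of 0.16 and no shift, the preset test gave an unadjusted p under 0.05 in 38% of runs. Over the called lists the estimated correlation ran from −0.141 (lymph node stroma) to 0.841 (smooth muscle). It was 0.287 for lipogenesis and 0.356 for immediate early genes. No correlation above 0.16 was simulated, so the 38% does not cover such lists. Single arrays moved the number of genes at an unadjusted p under 0.05. Between diabetic and normoglycemic fat it was 554 without normoglycemic 1, 1941 without normoglycemic 2, 745 without diabetic 1 and 766 without diabetic 2. Between AAT-treated and diabetic fat it was 1267 without AAT-treated 1 and 260 without AAT-treated 2. Between AAT-treated and normoglycemic fat it was 279 without normoglycemic 1 and 1512 without normoglycemic 2.

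Without the 2 arrays with the brightest hybridisation controls 24 of the 36 called lists kept camera's call, and the others lost it. Between diabetic and normoglycemic fat the lost ones were extracellular matrix (adjusted p = 0.169) and interferon response (0.113). Between AAT-treated and diabetic fat they were adipocyte identity (0.722), B cells (0.602), macrophages (0.0771), mesothelium (0.313) and oxidative phosphorylation (0.242). Between AAT-treated and normoglycemic fat they were adipocyte identity (0.133), clock genes (0.24), erythroid and platelet genes (0.0603), lipogenesis (0.526) and oxidative phosphorylation (0.455). In the same fit the medians of immediate early genes and lipogenesis in the first comparison were −1.0 and 1.55, and that of interferon response in the last was 0.25. With the hybridisation-control level as a covariate, medians in the first comparison were −0.25 for antioxidant genes, −2.96 for erythroid and platelet genes, −0.84 for immediate early genes and 0.35 for interferon response. That of mesothelium in the last was 1.34. With no filter the medians were 0.33 for lymph node stroma in the first comparison, 0.82 for erythroid and platelet genes in the second and 0.43 for MHC class II in the last.

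Camera with the preset correlation called none of the other 11 lists in any comparison. Median differences in the 3 comparisons, in the order above, were 0.13, −0.06 and −0.02 for insulin signalling and −0.32, −0.16 and −0.28 for fasting and fatty acid oxidation. They were −0.16, −0.23 and −0.29 for brown fat and 0.39, −0.20 and 0.20 for ER stress. For T cells they were −0.01, 0.17 and 0.03, for neutrophils −0.31, 0.06 and 0.24, and for inflammation 0.25, 0.12 and 0.12. Measured were 15 of 31 listed T cell genes, 8 of 17 neutrophil genes and 24 of 43 inflammation genes. Cd3e, Cd4, S100a9 and Ly6g were not kept, so these medians do not show that the cells or inflammation were unchanged. Endothelial genes gave 0.56, −0.20 and 0.39, and skeletal muscle genes −0.07, 0.36 and 0.12. Pancreas genes gave −0.22, 0.15 and −0.48, and mammary epithelium genes −0.23, 0.62 and 0.42. Of these 33 medians 24 took the other sign without 1 of the arrays. The endothelial list did so without normoglycemic 1 (−0.84 in the first and −0.90 in the last comparison), AAT-treated 2 (0.84 in the second) and AAT-treated 1 (−0.67 in the last). The smallest adjusted p of this camera test among them was 0.0684 (pancreas), and of these lists fry's test for change in either direction called fasting and fatty acid oxidation, as given above. The mean log2 level of the 3 measured Serpina1-list genes was 8.69 ± 0.37 (SD, n = 2) in normoglycemic, 9.83 ± 1.41 in diabetic and 9.33 ± 0.29 in AAT-treated fat. One of them, Serpina3n, is not a Serpina1 gene, and the others differed in pattern. Signals of Serpina1b were 30.0 and 231 in normoglycemic, 683 and 1438 in diabetic and 1593 and 456 in AAT-treated fat. Those of Serpina1c were 633 and 273, 258 and 1160, and 100 and 740. The median, mean and camera direction differed in sign for adipocyte identity, oxidative phosphorylation and brown fat in the first comparison. They did so for cell cycle, fasting and fatty acid oxidation, inflammation, neutrophils and pancreas in the second, and for B cells, insulin signalling and neutrophils in the third. Camera called none of these lists where its signs differed, while fry's test for change in either direction called cell cycle and fasting and fatty acid oxidation in the second comparison.

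Genes that differed in diabetic fat mostly differed the opposite way between AAT-treated and diabetic fat. Of the 1291 genes at an unadjusted p under 0.05 in the first comparison, 92.6% had the opposite sign in the second. Simulated unchanged groups that share the diabetic arrays gave 93.3%. Across genes, which are not independent replicates, the differences correlated at −0.566, against −0.50 (−0.517 to −0.484) over 1000 simulated draws. Their covariance was −0.189 against a simulated −0.110. The bright arrays are 1 normoglycemic and 1 AAT-treated array, so a deviation they share enters these comparisons with opposite signs. With the hybridisation-control level as a covariate the correlation was −0.510, against −0.529 (−0.544 to −0.511) in unchanged groups simulated in that design. Without the 2 bright arrays it was −0.467 against a simulated −0.334 (−0.349 to −0.315). Without AAT-treated 2 it was −0.205, weaker than the simulated −0.408, and without diabetic 1 or 2 it was −0.681 or −0.645 against −0.667. Without AAT-treated 1, normoglycemic 1 or normoglycemic 2 it was −0.628, −0.586 or −0.423, against −0.409. With the diabetic arrays split so that the comparisons shared none, at 1 array each, it was −0.221 and −0.192. The covariance was −0.143 with the covariate, against a simulated −0.108, and −0.310 without diabetic 1, against −0.244. Without AAT-treated 2 the covariance was −0.066, weaker than the simulated −0.099.

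In both comparisons 245 genes had an unadjusted p under 0.05, and 242 of them had opposite signs, where 100 simulated draws of unchanged groups sharing the diabetic arrays gave 162 (143 to 189). The draws treat genes and arrays as independent, so this and the other simulated ranges are too narrow, and the observed number is not shown to exceed that of unchanged groups. Of the 242 genes, 101 were higher and then lower, among them Insig1, Acss2 and Acly, against 79.7 simulated (65 to 97.6). The other 141 were lower and then higher, among them Egr1, Fos and Anp32a, against 82.1 simulated (68.5 to 103). Independent lists, which leave out the shared arrays, would share 12.6 and 17.7, and part of the excess over these may come from the shared arrays.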

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

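The tests of RNA integrity, of the share of adipocytes and of blood vessels were chosen only after the result was seen. The hybridisation-control covariate was chosen after seeing the data, and it and the test of other smooth-muscle tissue were chosen before their own values were seen. The further smooth-muscle and pericyte lists were written after the results of the 31 lists were seen. The spread against which each value was read was the standard error between arrays or the SD within groups. It was settled after the values were seen, and it left the share of adipocytes, blood vessels and plasma cells open. A reading without it would have excluded them. Unless said otherwise, an SE beside a list median is that of the difference between groups in the list's mean level.

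The beta-actin 3'/5' signal ratio of the control probe sets, which no comparison uses, had a mean of 15.3 on the diabetic arrays against 3.96 on the normoglycemic arrays.

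Lipogenic genes were higher in diabetic fat than in both other groups. An RNA integrity effect linear in the log2 beta-actin ratio would put the AAT-treated mean on the line through the other groups. It lay off that line by −0.87 (within-group SD 0.32), which argues against a linear integrity effect as the only cause. Linearity was not tested, so an integrity effect only at the high ratios of the diabetic arrays stays open. Whether integrity raised the diabetic over the normoglycemic values stays open, since the beta-actin ratio separates these groups too. Hybridisation brightness as the whole cause was argued against too, since with it as a covariate the median of AAT-treated against diabetic fat was −1.71 (SE 0.37; −1.50 without it). A higher share of adipocytes in the diabetic samples stays open: 20 adipocyte genes off the lipogenic list had medians of 0.16 and −0.48 in the comparisons with diabetic fat, against an SE between arrays of 0.76. The mice's diabetes and its reversion are candidate explanations that the design gives, untested apart from age or other differences between the groups.

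Smooth muscle genes were higher in AAT-treated fat. The AAT-treated mean lay 2.42 off the line (within-group SD 0.79), above both other groups, while the beta-actin ratio lay between theirs. This argues against an integrity effect that only rises or only falls with that ratio as the only cause. Other smooth-muscle tissue or cells in the samples may account for it. Of 23 further smooth-muscle genes, 23 were higher than in diabetic fat, with a median of 1.17 (SE 0.48). A rise in the fat's own smooth muscle would show the same, so this test does not tell them apart. More blood vessels stay open, with a median of −0.20 for endothelial genes (SE 1.39; 0.84 without AAT-treated 2 and −1.18 without AAT-treated 1) and −0.30 for pericyte genes, 1 of 9 of them higher. An effect of AAT treatment on smooth muscle stays open, as untested.

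Immediate early genes were lower in diabetic fat. With hybridisation brightness as a covariate the median was −0.84, against −0.32 without the covariate, so the shift did not shrink. The SE of 0.63 is too wide to exclude brightness as the whole cause. RNA integrity stays open, since the AAT-treated mean lay 0.59 off the line against a within-group SD of 0.50. Diabetes itself stays open as an explanation, as untested.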

How the results depend on the processing

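The crossed replicate block, the hybridisation-control covariate and the fit without the 2 arrays with the brightest hybridisation controls were chosen after seeing the data. Of 540 values of the 36 called lists under alternatives, 437 kept camera's direction and call, 101 lost the call and in 2 camera's direction reversed. List medians took the other sign in 8 values, 6 of them with camera's direction kept. Of 3705 values of named genes, 3652 kept direction and side of the threshold, 2 passed it and 51 reversed. No gene passed in the main fit, so a gene that stayed under the threshold counts as kept whatever its change in size. Without 1 of the arrays 23 of 54, 29 of 57 and 44 of 75 differences moved by over 1.5 times. The number of arrays limits precision, and a lone array was assumed to vary like the other groups. The cause was not tested for any change given here, apart from fewer arrays.

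With an estimated inter-gene correlation camera called 0, 0 and 0 lists, and without the 2 bright arrays 7 lists between AAT-treated and diabetic fat. By limma 1 gene between AAT-treated and diabetic fat passed at an adjusted p under 0.10 and 1 with no filter, both times Anp32a (adjusted p = 0.0749 and 0.0417, with a range of 0.0417 to 0.872 over 20 alternatives). Leaving out arrays gave 0 to 3 genes between AAT-treated and normoglycemic fat (Ephx1, Phf3 and Myh11 without normoglycemic 2, chosen after their values were seen). The correlation for the reversal of the diabetic changes ran from −0.681 (without diabetic 1) to −0.205 (without AAT-treated 2), where unchanged groups simulated in these designs gave −0.667 and −0.408.

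Arrays of one number correlated in their deviations at 0.0752, −0.506 and −0.116, which gives no sign that the numbers pair them. The 2 bright arrays carry unlike numbers, so a deviation they share could hide a pairing. The replicate block called 0, 0 and 0 genes and 10, 12 and 15 lists. The crossed replicate block called 0, 0 and 1 genes and 11, 11 and 15 lists.

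Values that reversed are given in the order diabetic against normoglycemic, AAT-treated against diabetic, AAT-treated against normoglycemic. With the covariate Irs1 was at 0.30, −0.11 and 0.20, Irs2 at −0.32, 0.25 and −0.072, Insr in the last at −0.067 and Lep in the first at −0.26. Without the 2 bright arrays Lep was at −0.54, 1.30 and 0.76 and Irs1 in the first and second at 0.084 and −0.30. In the second, Irs2 was then at 0.67, Krt19 at −0.14, Insr at 0.17 and Adipoq at 0.018. In the last, Hlf was at −0.21, Slc2a4 at 0.48 and the lipogenesis list at 0.10, and in the first Mfge8 at −0.090. Median centring put Irs1 at 0.0061 in the first and 0.030 in the last. Quantile normalization put Irs1 at −0.010 in the second and Scd1 at 0.17 in the first. Lep in the first was at −0.46 with no pseudocount and −0.016 with 1 that was 4 times smaller.

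The 6 list medians that took the other sign with camera's direction kept were 0.0045 for adipocyte identity, −0.28 for B cells and 0.02 for macrophages in the second comparison and 0.03 for lipogenesis in the last. Those of adipocyte identity and B cells came both without AAT-treated 2 and without the 2 bright arrays, that of macrophages without diabetic 2 and that of lipogenesis without AAT-treated 2.

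Leaving out arrays, the first comparison gave ranges of −1.16 to 0.12 for Adipoq, −0.19 to 0.15 for Irs1, −2.85 to 3.82 for Lep, −0.090 to 1.33 for Mfge8 and −0.72 to 0.0077 for Scd1. The second gave −1.13 to 0.14 for the adipocyte_identity list, −1.13 to 0.15 for Adipoq, −1.29 to 0.17 for Insr, −0.30 to 0.30 for Irs1, −0.88 to 0.67 for Irs2, −0.14 to 2.17 for Krt19 and −4.06 to 2.60 for Lep. The last gave −0.28 to 1.18 for Insr, −0.32 to 0.28 for Irs1, −0.14 to 1.40 for Irs2, −2.29 to 1.79 for Lep and −0.82 to 0.42 for Slc2a4.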

Other observations

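The genes of the first paragraph were picked, and the Ighm and Jchain pattern was noticed, after their values were seen; the tests of plasma cells and of the pairings were chosen before their results were seen, apart from the plasma cell values against diabetic fat.

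Camera did not call the list of fasting and fatty acid oxidation genes. Of its 21 genes 13 were lower between diabetic and normoglycemic fat (median −0.32). Between AAT-treated and diabetic fat 12 were lower (median −0.16), the direction of the lipogenic genes there. Single arrays moved both medians. The first was −0.11 without normoglycemic 1 and −0.61 without normoglycemic 2, and the second was −0.0021 without AAT-treated 1. In 3 members, picked for it, the differences ran opposite to those of the lipogenic genes in both comparisons. Pck1, which feeds glyceride-glycerol and glucose synthesis, differed by −1.31 ± 0.52 between diabetic and normoglycemic fat and by 1.45 ± 0.52 between AAT-treated and diabetic fat. Pdk4 differed by −1.37 ± 0.32 and 2.32 ± 0.32, and the electron transfer gene Etfdh by −1.21 ± 0.34 and 1.12 ± 0.34. None passed the adjusted threshold over all genes. Fry's test for change in either direction called the list between AAT-treated and diabetic fat (adjusted p = 0.0245), and camera did not (adjusted p = 0.987).

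Plasma cells in AAT-treated fat may be a source of Ighm (4.89 ± 0.86 against normoglycemic fat) and Jchain. The adjusted p of Ighm by limma ran from 0.0349 to 0.9998 over 20 alternatives. Of 10 other plasma cell genes 6 were higher than in normoglycemic fat, with a median of 0.17 (SE between arrays 0.39), and 7 were higher than in diabetic fat, with a median of 0.75. Against normoglycemic fat Igha differed by 2.87 and Mzb1, which the B cell list also holds, by 1.5, but Igk by 0.21 and Irf4 by −0.47. Against diabetic fat Irf4 differed by 1.99 (unadjusted p = 0.0201 by limma), Igha by 1.29, Mzb1 by 0.95 and Igk by 0.55. The hypothesis stays open.

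The 6 arrays can be put into 3 groups of 2 in 15 ways, too few for a share under 0.05. The real groups called 36 lists over the 3 comparisons, which 1 pairing (the real one) reached, and the highest other pairing called 35. The real groups called 0 genes by limma at the adjusted threshold, with 2581 at an unadjusted p under 0.05 over the 3 comparisons. The pairings that joined normoglycemic 1 with AAT-treated 2, the arrays with the brightest hybridisation controls, called 23, 25 and 120 genes, with 4972, 4661 and 5511 at an unadjusted p under 0.05. This points to a structure of the samples that the groups do not follow.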
